A study of Mus musculus with 4 samples.

How the data were processed

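The deposited data are raw UMI counts per gene and barcode, 1 matrix per library, from a 10x Genomics 3' gene expression assay on Hoechst-sorted nuclei of frozen ventricles. The submitters' processing notes name Cell Ranger 7.1 and the GRCm39 genome build, and the authors' pipeline had called the barcodes. No cell annotation came with the counts, so cell classes were rebuilt from the counts. Each library pools 2 hearts (sedentary, running) or 4 hearts (sedentary infarct, running infarct) of both sexes, and nothing in the matrices tells the hearts apart. The matrices list 25906 genes, of which 25461 were found by identifier in the GENCODE vM21 table, used only for gene names and Y linkage, and 37 are mitochondrially encoded. Genes carry the deposited symbols, in which Bmal1 is Arntl, and 18 symbols occur more than once. The genes fixed for every comparison were Nppa (ENSMUSG00000041616), Nppb (ENSMUSG00000029019), Myh7 (ENSMUSG00000053093) and Ankrd1 (ENSMUSG00000024803) in cardiomyocyte-like and Postn (ENSMUSG00000027750) and Col1a1 (ENSMUSG00000001506) in fibroblast-like nuclei.

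Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept. The planned limit of 5% was replaced after the distribution was seen, because it would have removed 65.5, 91.8, 45.5 and 44.1% of barcodes, and serves as an alternative. Doublets were scored per library with Scrublet in scanpy. Its automatic threshold called 0 doublets in each library, so the barcodes with the highest scores were removed at the usual loading rate, 0.8% per 1000 barcodes, which took 228, 301, 82 and 192. This left 5114, 5832, 3124 and 4711 nuclei. Counts were scaled to 10000 per nucleus and logged, and 3000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 gave the clusters, all libraries together without integration. A cluster took the name of the cell type, out of 17 with 160 markers, whose markers had the highest mean log2 excess over the mean of all clusters, if that was at least 1 and at least 3 markers had a UMI in 10% of its nuclei. It stayed unnamed if its 10 leading genes held more markers of another type, or if its depth was low and they held no own marker. Clusters with a median doublet score of 0.1 or more stayed unnamed, a limit set after the scores were seen. These mixed clusters held 9.54, 10.4, 11.7 and 11.1% of nuclei, and clusters of low depth without markers 10.9, 13.6, 7.78 and 10.5%. With doublets kept, mixed clusters were also open to naming, so shifts there can come from either. Macrophage-like cluster 8, at 0.099, fell just under the limit and was kept. It held 0.802, 0.840, 0.864 and 0.106% of nuclei, and without it the macrophage-like share was 2.70, 3.22, 7.52 and 13.8%.

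Raw counts were summed per library and class and divided by the class total without mitochondrially encoded genes to give counts per 1000000 (CPM). With 1 library per group no test was run. CPM carry exact Poisson intervals, ratios exact conditional binomial ones, and shares exact Clopper-Pearson ones, all at 95%. Share ratios carry an interval on the log scale. A gene entered with at least 100 UMIs over both libraries of a comparison. Gene lists, 30 in number, were fixed with the cell markers, the comparisons and the rule for naming genes before the data were examined. A list is described by the median log2 ratio of its measured members, by how many were at least 1.5-fold higher or lower, and by the percentile of the median among 10000 random lists matched on expression in 20 bins, a description of these libraries and not a test. The naming rule took, per comparison and main class, the 3 genes higher and the 3 lower with the interval bound farthest from even. They had to move the same way in Y-positive and Y-negative nuclei, in place of the planned sex calls. They could stand in no other class with 100 nuclei per library at over 5 times the CPM in either library. Y-linked and mitochondrially encoded genes and gene models with only a number were left out. A list member with 0 UMIs in 1 library was set to 3 counts for the median. List examples were members whose interval lay wholly beyond 1.5-fold, or else those with most UMIs. Genes that lead a cluster can be named by these rules too.

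The planned split by sex used Xist, which is not used here. Nuclei were instead called Y-positive with at least 2 UMIs of 4 Y-linked genes and Y-negative with 0, and a mixture with a negative binomial term (fitted size 3) gave the male percentage of each class. Sex and heart cannot be told apart within a pool. Nuclei were thinned to 1000 UMIs before the share with a UMI was compared. The concentration of a gene's UMIs in its top 10 nuclei was computed after the values of Fgf12 had been seen. The alternatives fixed with the design were all barcodes, a filter of at least 800 genes and at most 1% mitochondrial UMIs, doublets kept, Leiden resolutions of 0.5 and 2, each library clustered alone, other denominators, size factors by median of ratios, totals with mitochondrial genes, minima of 20 and 500 UMIs, equal weights per nucleus, a background limit of 2 and unthinned nuclei. Chosen after seeing the data were the 5% mitochondrial limit as an alternative, at least 800 genes alone, a doublet-score limit of 0.09 for clusters, named nuclei as denominator, the Y-linked splits and weights, no nuclei over 20000 UMIs, and leaving out the low-depth clusters or, in lists, members read as background. The first form of the test of free RNA behind the heat shock values set the CPM added in vascular endothelial-like against cardiomyocyte-like nuclei, with a limit of 2. It gave 2.04 and was replaced, after that value was seen, by the highest over the lowest of the 4 main classes.

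On simulated counts with 200 changed genes, the intervals held the true ratio in 95.3 to 96.0% of genes, and lists with no change fell outside the random range in 4.75% of cases. Another scaling moved the median of all genes by at most 0.06 on the log2 scale. The work used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.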

Results

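Nuclei from frozen mouse ventricles were profiled by single-nucleus RNA sequencing in a design that crosses voluntary wheel running with myocardial infarction. C57BL/6J mice of both sexes ran for 16 weeks or stayed sedentary. Hearts were then taken from 2 mice per arm, and from 4 mice per arm 2 weeks after infarct surgery. The hearts of a group were pooled and loaded in 1 well, so each of the 4 groups has 1 library (n = 1), no comparison was tested, and differences are described as values of these libraries. The sedentary, running, sedentary infarct and running infarct libraries, always given in this order, held 5388, 6253, 3243 and 4922 barcodes and 32899707, 37533722, 26170995 and 29916572 unique molecular identifiers (UMIs). The median was 3596.5, 3811, 4214 and 2910.5 UMIs per barcode. Ranges in brackets are 95% intervals that cover counting error only, not differences between animals.

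After filtering, 5114, 5832, 3124 and 4711 nuclei remained and 11 cell classes were named from markers. Cardiomyocyte-like nuclei made up 15.1, 11, 11.6 and 8.28% of them, fibroblast-like nuclei 28.0, 26.3, 29.0 and 16.2%, vascular endothelial-like nuclei 16.7, 16.6, 12.6 and 18.5% and macrophage-like nuclei 3.50, 4.06, 8.39 and 13.9%. Nuclei had been sorted on Hoechst, a DNA stain, before loading, and depth differed between libraries, both of which can set such shares. Median depth was 8465, 8479, 9545 and 3452 UMIs in cardiomyocyte-like, 3478.5, 4022, 4435 and 4389 in fibroblast-like, 2436, 2584, 2473 and 1618 in vascular endothelial-like and 3269, 3265, 3107 and 2150.5 in macrophage-like nuclei. A low-depth cluster supplied 5.84, 8.09, 14.4 and 42.1% of the cardiomyocyte-like class, and another supplied 35, 44.9, 54.7 and 71.8% of the vascular endothelial-like class. Mitochondrially encoded transcripts took 5.07, 7.67, 4.89 and 4.43% of UMIs in cardiomyocyte-like and 5.79, 9.98, 3.28 and 3.31% in fibroblast-like nuclei, highest in the running library. A model of Y-linked UMIs put 64.4, 72.4, 30.0 and 41.6% of named nuclei as male, so the libraries also differed in the sex of their nuclei. Selected values are also given for Y-positive nuclei, which are male, and Y-negative nuclei, which by the same model still hold 35.1, 42.6, 9.96 and 21.0% male nuclei.

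**Figure D1:**
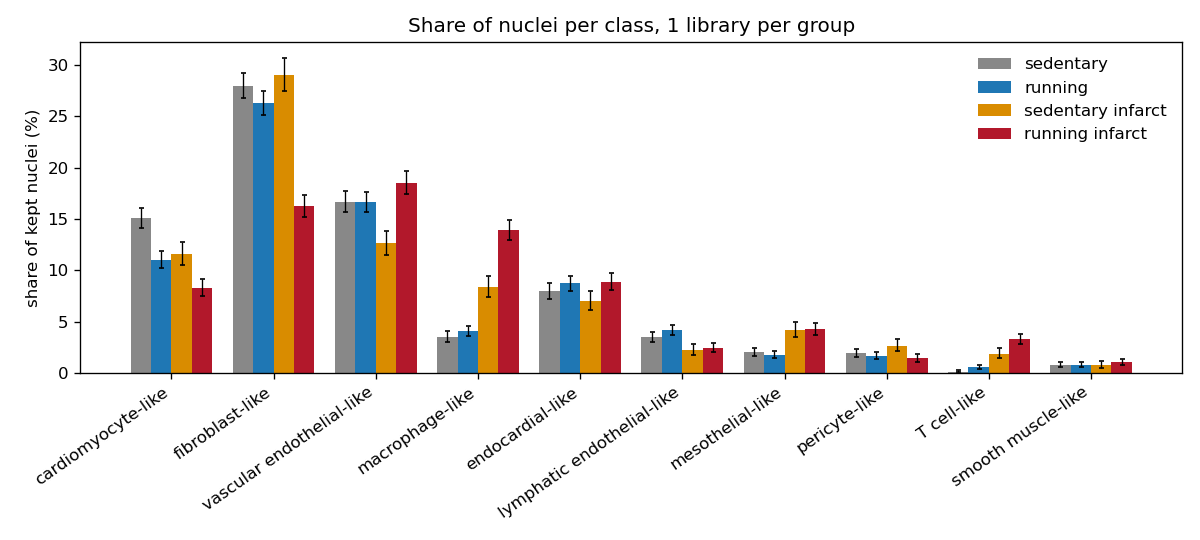
Share of kept nuclei (percent) in the main classes of the 4 libraries, with exact 95% binomial intervals as bars. The macrophage-like share was 3.50% in the sedentary and 13.9% in the running infarct library.

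The comparison of the sedentary infarct with the sedentary library asks what the ventricles held 2 weeks after infarction in mice that had not run. Cardiomyocyte-like nuclei carried more RNA of the natriuretic peptide gene Nppb, 5.28-fold higher (4.56 to 6.12), and of the stretch-responsive cofactor gene Ankrd1, 9.94-fold higher (9.38 to 10.5). The other natriuretic peptide gene, Nppa, was 20.8-fold higher (16.8 to 26.1), but it also rose from 11.2 to 197 CPM in vascular endothelial-like nuclei, where it is read as background RNA. Fibroblast-like nuclei carried more of the matricellular gene Postn, 8.80-fold higher (8.15 to 9.52), and of the type I collagen gene Col1a1, 2.55-fold higher (2.33 to 2.81). The macrophage-like share was 2.40 times as large, with more of the chemokine receptor gene Ccr2, 6.42-fold higher (4.24 to 10.1), and less of the resident macrophage gene Lyve1, 2.5-fold lower (1.86 to 3.39). Lyve1 was not checked for background against lymphatic endothelial-like nuclei.

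In cardiomyocyte-like nuclei, 9 of 12 measured stress and fetal cardiac genes were at least 1.5-fold higher and 0 lower (median log2 ratio 1.31, above all 10000 matched random lists). That median was 0.68 in Y-positive nuclei, 0.82 with doublets kept and 0.85 over genes with at least 500 UMIs. Besides the natriuretic peptides, skeletal alpha-actin, Acta1, was 6.38-fold higher (5.08 to 8.08), while the slow myosin heavy chain gene Myh7 was near even at 1.12-fold higher (1.08 to 1.16) and reversed to a log2 ratio of -0.26 with doublets kept. Nppa UMIs were concentrated: 10 nuclei held 52.2% of those in the sedentary infarct and 78.0% in the sedentary library, where 1 nucleus had 53 of 91 UMIs. Its log2 ratio of 4.38 became 2.67 with every nucleus weighed the same, 5.79 at 5% mitochondrial UMIs, 5.75 with at least 800 genes and 5.48 in Y-positive nuclei. Fatty acid oxidation genes were lower (6 of 25 at least 1.5-fold lower, median -0.33, below all 10000 matched random lists), among them Pdk4, which restrains glucose oxidation, 4.44-fold lower (3.85 to 5.14), and the uncoupling protein gene Ucp3, 3.27-fold lower (2.57 to 4.2). Of the genes of glycolysis and glucose uptake, 3 of 17 were at least 1.5-fold higher (median 0.37, above all 10000 matched random lists), but the median was 0.10 in Y-positive and 0.51 in Y-negative nuclei. The phosphofructokinase gene Pfkp was 2.45-fold higher (2.07 to 2.89). Irs2, an insulin receptor substrate gene, was 5.44-fold lower (4.17 to 7.21), or -1.39 on the log2 scale with doublets kept. The sarcomere and Z-disc list had a median of 0.04 with 3 of 20 genes higher, including the titin cap gene Tcap, 2.21-fold higher (2.05 to 2.37), and the myosin-binding gene Mybpc3, 1.59-fold higher (1.52 to 1.66). The medians were -0.11 for nuclear-encoded oxidative phosphorylation and 0.05 for calcium handling. With doublets kept, those of the sarcomere and calcium lists were -0.31 and -0.31.

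In fibroblast-like nuclei, 15 of 16 myofibroblast activation genes (median 2.63, above all 10000 matched random lists) and 14 of 24 collagen and extracellular matrix genes (median 0.70, above all 10000 matched random lists) were at least 1.5-fold higher, and 0 of either list lower. Examples were the secreted matrix gene Cthrc1, 43.4-fold higher (19.6 to 119.5), the matrix gene Tnc, 26.3-fold higher (13.6 to 58.4), the transcription factor gene Runx1, 14.4-fold higher (11.6 to 18.1), the fibronectin gene Fn1, 7.72-fold higher (6.83 to 8.75), and the fibrillar collagen gene Col11a1, 41.1-fold higher (20.5 to 96.0). Runx1 stood at 17.5 and 251 CPM here against up to 1272 and 1197 CPM in another class. The hyaluronan-degrading gene Cemip, 32.8-fold higher (17.0 to 72.7), had 85.7% of its UMIs in 10 nuclei. TGF-beta signalling genes were higher (7 of 14 measured genes at least 1.5-fold higher and 1 lower, median 0.52, above all 10000 matched random lists), with Ccn2, a target of that pathway, 5.08-fold higher (4.45 to 5.83), and the thrombospondin gene Thbs1, 5.96-fold higher (4.65 to 7.71). Wnt modulators and matrifibrocyte genes had a median of 0.99, percentile 99.99, or 1.66 over genes with at least 20 UMIs, led by Sfrp2, 14.4-fold higher (8.21 to 27.7). Homeostatic fibroblast genes were lower (10 of 17 at least 1.5-fold, median -0.69, below all 10000 matched random lists), with the ferritin receptor gene Scara5 2.88-fold lower (2.64 to 3.15) and G0s2, an inhibitor of lipolysis, 3.46-fold lower (2.83 to 4.26). The receptor tyrosine kinase gene Ret was 7.09-fold lower (5.46 to 9.34), Tmprss11a 7.41-fold lower (4.93 to 11.6) and the cell adhesion gene Opcml 3.76-fold lower (3.32 to 4.27). Different clusters held the class: the one led by Postn, Col12a1, Col11a1 and Cthrc1 supplied 1.12, 1.57, 30.1 and 43.1% of fibroblast-like nuclei, and the largest resting one, number 0, 68.5, 65.1, 32.6 and 20.9%.

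In vascular endothelial-like nuclei, angiogenesis and tip-cell genes were higher (6 of 13 measured genes at least 1.5-fold higher and 0 lower, median 0.39, percentile 99.97), including the basement membrane genes Col4a1, 1.67-fold higher (1.51 to 1.85), Col4a2, 1.96-fold higher (1.74 to 2.20), and Nid2, 2.49-fold higher (1.73 to 3.6), and the guidance receptor gene Unc5b, 2.37-fold higher (1.77 to 3.17). Arterial genes were lower (4 of 10 at least 1.5-fold, median -0.32, percentile 0.11), with the gap junction gene Gja5 3.01-fold lower (2.21 to 4.19) and Sema3g 2.43-fold lower (1.86 to 3.24). Flow response and vasomotor genes had a median of -0.26, percentile 0.73, with the shear-induced factor Klf2 1.89-fold lower (1.62 to 2.21), and endothelial fatty acid handling genes one of -0.34, percentile 0.24, with the transport regulator Meox2 1.78-fold lower (1.65 to 1.93). The arterial cluster led by Gja5 and Sema3g supplied 23.4, 22.2, 8.10 and 4.94% of the class. Nppa, at 11.2 and 197 CPM, and Col1a1, at 26.8 and 161 CPM, were the most raised genes by the naming rule, yet the same RNAs stood at 294 CPM in cardiomyocyte-like and 325 CPM in fibroblast-like nuclei of the infarct library, so both are read as background RNA, as is Nppa in macrophage-like nuclei, at 9.58 and 159 CPM.

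Macrophage-like nuclei made up 3.50% (3.01 to 4.04) of the sedentary and 8.39% (7.44 to 9.41) of the sedentary infarct library, a ratio of 2.40 (1.99 to 2.88), or 1.40 with each library clustered alone. The T cell-like ratio was 13.6 (6.20 to 29.7), from 7 nuclei in the sedentary library, in a cluster that Pax5, a B cell gene, also led. The mesothelial-like ratio was 2.08 (1.61 to 2.68). The cardiomyocyte-like ratio was 0.769 (0.684 to 0.864), or 0.428 with at most 5% mitochondrial UMIs and 0.503 in female-weighted nuclei. The vascular endothelial-like one was 0.759 (0.679 to 0.848), which reached 1.00 at that limit, and the fibroblast-like one 1.04 (0.968 to 1.11). Within macrophage-like nuclei, monocyte-derived and inflammatory genes were higher (4 of 6 measured genes at least 1.5-fold higher and 1 lower, median 0.75, above all 10000 matched random lists), although the median was -0.03 in nuclei with at least 800 genes. Lipid-associated and phagocytic genes had 3 of 10 higher (median 0.32, percentile 98.9), with the galectin gene Lgals3 4.33-fold higher (2.80 to 6.97) and Gpnmb, a glycoprotein gene of lipid-laden macrophages, 83.8-fold higher (14.7 to 3338) from 1 UMI in the sedentary library, with 79.5% of its later UMIs in 10 nuclei. The list median was 0.02 in Y-positive and 0.18 in Y-negative nuclei. Resident macrophage genes were lower (4 of 10, median -0.53, percentile 0.02), but the median was -0.03 in Y-positive and -0.76 in Y-negative nuclei. The scavenger receptor gene Cd163 was 1.92-fold lower (1.68 to 2.20). The transcription factor gene St18 was 26.5-fold higher (12 to 73.0), Adhfe1 4.58-fold lower (3.28 to 6.52) and the co-chaperone gene Stip1 3.70-fold lower (2.62 to 5.32). The lipid-associated median turned to -0.06, and the glutathione transferase gene Gsta3 moved from -2.00 to -0.30, once cluster 8, a macrophage-like cluster close to the doublet limit, was left out.

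Heat shock genes were lower in every main class, with medians of -1.24 in cardiomyocyte-like, -1.45 in fibroblast-like (-2.04 in Y-positive nuclei), -1.95 in vascular endothelial-like and -1.46 in macrophage-like nuclei. In cardiomyocyte-like nuclei the chaperone gene Hsph1 was 4.38-fold lower (3.31 to 5.91), with log2 ratios of -3.24 in Y-positive and -0.54 in Y-negative nuclei, and the list median was -2.11 in Y-positive and -0.45 in Y-negative nuclei. The inducible Hsp70 gene Hspa1a was 34.7-fold lower (11.7 to 169) in vascular endothelial-like nuclei, where 3 UMIs remained. Across the libraries Hsph1 stood at 203, 40.7, 35.6 and 27.2 CPM in that class, highest in the sedentary library. The clock output genes Dbp, 3.95-fold higher (3.21 to 4.87), and Nr1d1, 3.79-fold higher (2.71 to 5.36), were higher in cardiomyocyte-like nuclei, and their activator Arntl was 3.0-fold lower (2.11 to 4.37). Immediate early genes had medians of -0.55 in fibroblast-like and -1.03 in vascular endothelial-like nuclei. P4ha1, a hypoxia-responsive collagen hydroxylase gene, was 3.23-fold lower (2.74 to 3.82) in vascular endothelial-like nuclei. Abundant cardiomyocyte transcripts, which measure free RNA in other classes, had medians of -0.50 in fibroblast-like, -0.44 in vascular endothelial-like and -0.05 in macrophage-like nuclei. Of the values of genes taken by size or fixed beforehand, 10 of 24 moved by over 1.5-fold in Y-positive and 9 of 28 in Y-negative nuclei, and 7 of 28 with every nucleus weighed the same.

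The comparison of the running infarct with the running library asks the same question in mice that had run before infarction. Cardiomyocyte-like nuclei again carried more Nppa, 12.1-fold higher (9.78 to 15.1), Nppb, 6.49-fold higher (5.50 to 7.68), and Ankrd1, 3.71-fold higher (3.53 to 3.90), and less Pdk4, 11.6-fold lower (9.14 to 14.8), with log2 ratios of -4.49 in Y-positive and -1.06 in Y-negative nuclei. Fibroblast-like nuclei carried more Postn, 6.69-fold higher (6.21 to 7.21), Col1a1, 2.87-fold higher (2.62 to 3.14), and elastin, Eln, 9.00-fold higher (8.28 to 9.78), at 113 and 1017 CPM against up to 801 and 994 CPM in another class. The macrophage-like share went from 4.06% (3.57 to 4.60) in the running to 13.9% (12.9 to 14.9) in the running infarct library, and the fibroblast-like share from 26.3% (25.1 to 27.4) to 16.2% (15.2 to 17.3). Arterial endothelial genes were lower, with Gja5 3.93-fold lower (2.95 to 5.33) and Sema3g 4.29-fold lower (3.21 to 5.82).

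In cardiomyocyte-like nuclei, 9 of 12 stress and fetal cardiac genes were at least 1.5-fold higher and 0 lower (median 1.72, above all 10000 matched random lists), including Acta1, 4.94-fold higher (3.90 to 6.28), and Ccn2, 5.00-fold higher (3.84 to 6.54). With doublets kept, the median was 0.96, and the log2 ratios of Nppa, Nppb and Ankrd1 were 2.75, 1.93 and 1.24 in place of 3.6, 2.70 and 1.89, and that of Myh7 was -0.44 in place of 0.20. Fatty acid oxidation genes were lower (7 of 24 at least 1.5-fold, median -0.33, below all 10000 matched random lists), but the median was -0.78 in Y-positive and -0.06 in Y-negative nuclei. Among them Ucp3 was 5.08-fold lower (3.50 to 7.62), with log2 ratios of -2.78 in Y-positive and -1.17 in Y-negative nuclei, and the mitochondrial biogenesis coactivator Ppargc1a 1.84-fold lower (1.75 to 1.94). The glycolysis list had 6 of 17 measured genes at least 1.5-fold higher and 1 lower (median 0.27, percentile 99.9, 0.12 in Y-positive and 0.00 in Y-negative nuclei, or -0.02 over genes with at least 500 UMIs). The hexokinase gene Hk1 was 1.92-fold higher (1.66 to 2.22). In the calcium handling list (median 0.13, percentile 97.6, or -0.34 with doublets kept), the sodium-calcium exchanger gene Slc8a1 was 1.81-fold higher (1.78 to 1.84) and the calsequestrin gene Casq2 1.67-fold higher (1.56 to 1.78). The nuclear receptor gene Nr4a1 was 10.0-fold lower (7.82 to 13), with log2 ratios of -4.08 in Y-positive and -1.43 in Y-negative nuclei. The small GTPase gene Rasl11b was 6.07-fold higher (4.19 to 8.93), or 1.48 on the log2 scale at 5% mitochondrial UMIs. The low-depth cluster held 8.09% of the class in the running and 42.1% in the running infarct library.

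In fibroblast-like nuclei, 14 of 16 myofibroblast activation genes (median 2.63, above all 10000 matched random lists) and 16 of 25 collagen and extracellular matrix genes (median 1.14, above all 10000 matched random lists) were at least 1.5-fold higher, and 1 and 0 lower. Cthrc1 was 39.3-fold higher (20.3 to 87.2), Col11a1 30.3-fold higher (21.2 to 44.7), the TGF-beta binding protein gene Ltbp2 11.8-fold higher (10.1 to 13.9), the collagen cross-linking gene Lox 10.4-fold higher (6.69 to 17.0) and Ddah1 20.7-fold higher (16.0 to 27.2). At most 5% mitochondrial UMIs, a limit that removed most nuclei of the running library, gave a myofibroblast median of 1.44 and log2 ratios of 1.16 for Postn, 2.62 for Col11a1 and 2.86 for Ddah1, in place of 2.74, 4.92 and 4.37. TGF-beta signalling genes had a median of 0.73, above all 10000 matched random lists (7 higher and 2 lower of 14) and Wnt modulators and matrifibrocyte genes one of 1.13, percentile 99.99 (4 higher and 0 lower of 6), with Sfrp2 10.4-fold higher (7.23 to 15.4). Homeostatic fibroblast genes were lower (12 of 17 at least 1.5-fold, median -1.02, below all 10000 matched random lists), with the methyltransferase gene Inmt 5.29-fold lower (4.10 to 6.94) and the cortisone-activating gene Hsd11b1 3.76-fold lower (3.06 to 4.66). The leptin receptor gene Lepr was 6.29-fold lower (5.19 to 7.69), the metalloprotease gene Tll2 9.53-fold lower (6.80 to 13.8) and the neutrophil chemokine gene Cxcl1 7.12-fold lower (4.56 to 11.7).

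In vascular endothelial-like nuclei, 7 of 14 angiogenesis and tip-cell genes were at least 1.5-fold higher (median 0.48, above all 10000 matched random lists). The low-depth cluster went from 44.9 to 71.8% of this class, and the median was 0.14 without it and 0.65 in Y-positive and 0.23 in Y-negative nuclei. Col4a2 was 3.91-fold higher (3.51 to 4.36), Col4a1 3.0-fold higher (2.75 to 3.27) and the fenestral diaphragm gene Plvap 3.0-fold higher (2.09 to 4.36). Arterial genes had 7 of 10 lower (median -0.76, below all 10000 matched random lists, or -1.64 at 5% mitochondrial UMIs) and flow response genes 5 of 10 lower and 1 higher (median -0.48, percentile 0.04). The retinoic acid-degrading gene Cyp26b1 was 24.5-fold lower (13.1 to 51.5), or -2.95 on the log2 scale at 5% mitochondrial UMIs, the calcium pump gene Atp2b2 8.12-fold lower (5.13 to 13.6), and Gkn3 42.3-fold lower (11.4 to 353) from 2 UMIs in the running infarct library. Cyp26b1 is a leading gene of cluster 11, which supplied 41.7, 32.9, 37.2 and 23.3% of the class, and Atp2b2 and Gkn3 lead the arterial cluster. Nppa (17.2 and 136 CPM) and Col1a1 (31.1 and 186 CPM) are again read as background RNA, as is Nppa in macrophage-like nuclei (11.9 and 114 CPM). Macrophage-like nuclei had 4 of 10 lipid-associated and phagocytic genes higher and 1 lower (median 0.51, percentile 99.8), with Gpnmb 27.9-fold higher (10.7 to 103), 52.4% of it in 10 nuclei, and the lysosomal protease gene Ctsd 2.31-fold higher (1.66 to 3.27). Resident macrophage genes had 5 of 10 lower (median -0.56, percentile 0.07, -0.25 in Y-positive and -0.46 in Y-negative nuclei), with Lyve1 3.83-fold lower (2.83 to 5.24) and the phosphatidylserine receptor gene Timd4 3.40-fold lower (2.55 to 4.57). Ccr2 was 3.79-fold higher (2.86 to 5.10) and St18 15.5-fold higher (9.29 to 28.0), and the monocyte-derived list had a median of 0.25, or -0.10 without cluster 8. The basement membrane gene Nid1 also depended on that cluster, at a log2 ratio of -1.99 with and -0.93 without it, whereas Adhfe1 was 3.73-fold lower (2.89 to 4.84).

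The share ratio was 3.42 (2.96 to 3.94) for macrophage-like nuclei, 12.3 in female-weighted and 2.53 in male-weighted ones. The 12.3 rests on few nuclei, as the model put 93.4% of macrophage-like nuclei of the running library as male. The ratio was 6.15 (4.19 to 9.03) for T cell-like, 2.42 (1.91 to 3.05) for mesothelial-like, 0.751 (0.666 to 0.846) for cardiomyocyte-like (0.487 male-weighted) and 0.617 (0.571 to 0.667) for fibroblast-like nuclei. For vascular endothelial-like nuclei it was 1.11 (1.02 to 1.21), but 0.984 with at least 800 genes, 0.857 in male-weighted nuclei and 0.525 at 5% mitochondrial UMIs. Outside its low-depth cluster that share was lower after infarction. Clock list medians were -0.53, -0.74, -0.77 and -1.34 in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei. The list holds more members that move with Nr1d1 than with Arntl. The macrophage-like clock median was -0.92 in Y-positive and -0.44 in Y-negative nuclei. The clock activator Arntl was 11.1-fold higher (8.64 to 14.5) in fibroblast-like nuclei, where its partner Npas2 was 5.65-fold higher (4.53 to 7.09). Heat shock medians were -0.22, -0.32, -0.49 and -0.40 in the same classes, and in the cardiomyocyte-like one -0.97 in Y-positive and -0.27 in Y-negative nuclei. Immediate early gene medians were -0.89, -0.81 and -1.06 in the former 3, or -2.12 in Y-positive nuclei of the first and -0.02 in the second at 5% mitochondrial UMIs. Abundant cardiomyocyte transcripts had medians of -0.63, -0.28 and 0.09 outside the cardiomyocyte-like class. Of the values of genes taken by size or fixed beforehand, 10 of 27 moved by over 1.5-fold in Y-positive and 10 of 28 in Y-negative nuclei, and 10 of 26 at 5% mitochondrial UMIs.

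**Figure D2:**
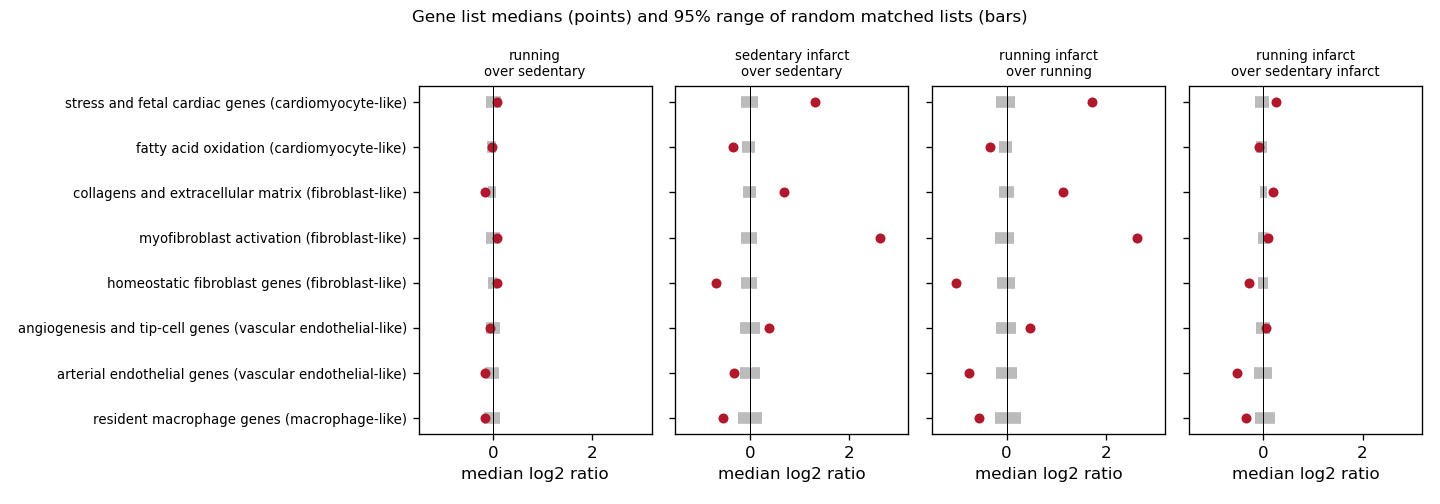
Median log2 ratio of 8 gene lists (points, horizontal axis) in the 4 comparisons, with the 95% range of 10000 matched random lists as grey bars. Myofibroblast activation genes in fibroblast-like nuclei had medians of 2.63 and 2.63 in the infarct comparisons and 0.09 and 0.08 in the others.

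The infarct responses of runners and sedentary mice were also set side by side. The runners' median minus the sedentary one was 0.00 for myofibroblast activation, 0.41 for stress and fetal cardiac genes and 0.44 for collagens and extracellular matrix. It was 0.00 for fatty acid oxidation, but in sedentary mice that median was -0.11 in Y-positive and -0.45 in Y-negative nuclei, and in runners -0.78 in Y-positive and -0.06 in Y-negative nuclei. Among single genes the log2 difference was -0.78 for Nppa and -1.42 for Ankrd1, which was already higher in the running than in the sedentary library, 0.30 for Nppb, -0.40 for Postn, 0.17 for Col1a1 and 1.74 for Eln. With every nucleus weighed the same, the log2 ratio of Nppa was 3.78 in runners and 2.67 in sedentary mice. This turns the sign of the Nppa difference. Its sedentary level is read as background. Arterial endothelial genes differed by -0.44, with a lower median in runners, and monocyte-derived macrophage genes by -0.50. With at least 800 genes, the monocyte-derived median was -0.04 in runners and -0.03 in sedentary mice. The ratio of the share ratios, runners over sedentary mice, was 0.595 for fibroblast-like, 1.43 for macrophage-like, 1.46 for vascular endothelial-like and 0.977 for cardiomyocyte-like nuclei. Clock lists differed by -0.87, -0.74, -1.09 and -1.30 in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei. Heat shock lists, already lower in the running than in the sedentary library, differed by 1.02, 1.13, 1.46 and 1.06. None of these differences was tested.

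Nuclei with a UMI were also counted after each nucleus was thinned to 1000 UMIs. Nppa was seen in 0.668, 2.08, 13.3 and 14.4% of cardiomyocyte-like nuclei against 1.13, 1.12, 12.3 and 5.82% of fibroblast-like nuclei, which should lack it, so the sedentary value is read as background and the sedentary infarct value stood close to it. Nppb was seen in 3.48, 2.72, 11.8 and 16.8% against 0.776, 0.658, 2.11 and 2.78%, Ankrd1 in 13.5, 24.8, 53.0 and 54.7% against 1.41, 4.61, 10.3 and 9.52% and Myh7 in 66.2, 69.1, 68.3 and 57.0% against 2.61, 1.58, 4.34 and 3.44%. Postn was seen in 5.78, 6.25, 40.2 and 37.4% of fibroblast-like against 0.535, 1.44, 5.62 and 10.4% of cardiomyocyte-like nuclei. Without thinning the percentages were 3.74, 6.56, 52.7 and 34.6 for Nppa, 15.6, 16.6, 42.0 and 47.7 for Nppb, 36.4, 57.9, 77.5 and 78.2 for Ankrd1, 93.9, 90.9, 91.1 and 77.9 for Myh7 and 13.5, 14.3, 62.7 and 64.2 for Postn. Thinning left out 23, 18, 24 and 92 cardiomyocyte-like and 12, 12, 8 and 8 fibroblast-like nuclei as too shallow.

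The comparison of the running with the sedentary library asks what running alone went with. Stress, collagen and myofibroblast lists had medians of 0.09, -0.17 and 0.09. Cardiomyocyte-like nuclei of the running library carried more of the nuclear receptor gene Nr4a1, 7.93-fold higher (6.97 to 9.06), the myosin light chain kinase gene Mylk4, 2.52-fold higher (2.39 to 2.66), and Ankrd1, 2.37-fold higher (2.22 to 2.53), and less of the magnesium transporter gene Slc41a3, 4.17-fold lower (3.23 to 5.43). The clock activator Arntl was lower in cardiomyocyte-, fibroblast- and vascular endothelial-like nuclei, 3.98-fold lower (3.04 to 5.27) in the second, where the repressor Nr1d1 was 2.74-fold higher (2.33 to 3.23). In Y-negative nuclei of these classes the Arntl log2 ratios were -0.25, -1.14 and -1.46. Heat shock genes were lower in all main classes, with Hspa1a 22.3-fold lower (12.2 to 45.3) in vascular endothelial-like nuclei.

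In cardiomyocyte-like nuclei the stress and fetal list had 1 of 12 measured genes at least 1.5-fold higher and 1 lower (median 0.09, percentile 89.0, or -0.31 in Y-positive and 0.37 in Y-negative nuclei), the lower gene being the filamin gene Flnc, 1.98-fold lower (1.77 to 2.22). Nppa was 1.41-fold higher (1.05 to 1.88), Myh7 1.16-fold higher (1.12 to 1.19) and Nppb near even at a log2 ratio of -0.03 (-0.30 to 0.24), while 1 nucleus held 53 of the 91 Nppa UMIs of the sedentary library. The log2 ratio of Nppa was -1.99 with every nucleus weighed the same, 2.05 at 5% mitochondrial UMIs, 1.67 with at least 800 genes, 1.18 without the low-depth cluster, and 1.73 in Y-positive and -0.59 in Y-negative nuclei. The exercise-linked growth signalling list had a median of -0.09, percentile 14.0, with 3 members above and 10 below 0 and 0 changed by 1.5-fold. Those above include Ppargc1a, 1.30-fold higher (1.27 to 1.34), and the neuregulin receptor gene Erbb4, 1.09-fold higher (1.06 to 1.12). Fatty acid oxidation had a median of -0.02, percentile 53.5, but 0.37 in Y-positive and -0.45 in Y-negative nuclei. Nuclear-encoded oxidative phosphorylation had a median of -0.03, percentile 61.1, and glycolysis one of 0.14, percentile 99.4, with Hk2 1.23-fold higher (1.17 to 1.30), although the glycolysis median was -0.17 in Y-positive nuclei. Immediate early genes were higher in cardiomyocyte-like (5 of 7, median 0.63, above all 10000 matched random lists, 1.39 in Y-positive and 0.31 in Y-negative nuclei) and fibroblast-like nuclei (4 of 9, median 0.38, above all 10000 matched random lists), including Egr1, 2.35-fold higher (1.97 to 2.81), and Junb, 2.17-fold higher (1.84 to 2.57), in the latter. Hypoxia response genes were lower (3 of 9, median -0.36, percentile 0.01), with the oxygen sensor gene Egln3 3.52-fold lower (2.84 to 4.39) and P4ha1 2.17-fold lower (1.93 to 2.45). Egln3 stood at 70.4 and 20.0 CPM in this class against up to 172 and 198 CPM in another, so part of it can be background RNA. The lower level was seen in Y-positive nuclei alone. In Y-positive and Y-negative nuclei the list median was -0.58 and 0.27, and the log2 ratio -3.27 and 1.00 for Egln3 and -2.20 and 0.32 for P4ha1. Nr4a1 (4.2 in Y-positive and 0.88 in Y-negative nuclei) and the stretch-induced gene Ankrd23, 2.66-fold lower (2.30 to 3.09) or -2.39 in Y-positive and -0.06 in Y-negative nuclei on the log2 scale, also rested mostly on Y-positive nuclei.

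Fibroblast-like nuclei had Postn at 145 and 148 CPM and Col1a1 at 127 and 131 CPM without and with running, log2 ratios of 0.02 (-0.12 to 0.17) and 0.04 (-0.11 to 0.20). Postn reached a log2 ratio of 1.24, and the myofibroblast list a median of 1.28, at 5% mitochondrial UMIs. The collagen and extracellular matrix median was -0.17, percentile 0.02, or 0.02 in Y-negative nuclei, with Eln 1.69-fold lower (1.53 to 1.87), at 191 and 113 CPM against up to 875 and 801 CPM in another class. The homeostatic list had a median of 0.08, percentile 98.5, of the other sign in Y-positive nuclei, -0.15, with Inmt 2.02-fold higher (1.74 to 2.36) and G0s2 1.76-fold lower (1.53 to 2.03). In vascular endothelial-like nuclei, 0 of 10 arterial (median -0.17, percentile 1.48) and 2 of 10 flow response genes (median -0.16, percentile 1.57) were at least 1.5-fold lower, with both medians above 0 at 5% mitochondrial UMIs (0.18 and 0.09). The vasoconstrictor gene Edn1 was 2.07-fold lower (1.64 to 2.62), with a log2 ratio of 0.38 at that limit. The angiogenesis median was -0.06, percentile 18.5. In macrophage-like nuclei monocyte-derived genes had a median of 0.49, percentile 99.96, or 0.04 with at least 800 genes. Lipid-associated genes had one of -0.33, percentile 0.155, or 0.03 over genes with at least 20 UMIs. The antigen presentation gene Cd74 was 1.40-fold higher (1.16 to 1.68) and the lipid transport gene Apoe 1.37-fold lower (1.2 to 1.56). There Mthfd1l was 2.45-fold higher (1.70 to 3.59), the co-chaperone gene Stip1 2.76-fold lower (2.00 to 3.86), Mfsd6 2.22-fold lower (1.60 to 3.10) and Rgs7bp 2.85-fold lower (1.86 to 4.47), the last -0.69 on the log2 scale with at least 800 genes.

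The globin genes Hbb-bt, 6.39-fold higher (4.5 to 9.32), and Hba-a2, 5.52-fold higher (4.43 to 6.93), were higher in vascular endothelial-like nuclei of the running library, where 10 nuclei held 72.3% of Hbb-bt UMIs. In fibroblast-like nuclei Hba-a1 was 2.62-fold higher (2.18 to 3.16) and Hba-a2 2.55-fold higher (2.08 to 3.15), with log2 ratios of 0.41 and 0.29 once doublets were kept. Globin RNA stood higher in the running library in every named class, for instance at 203 against 77.5 CPM in cardiomyocyte-like and 669 against 193 CPM in endocardial-like nuclei, so part of it can be background RNA. Grik1 and Lrp1b, the former 2.69-fold higher (2.24 to 3.23) in cardiomyocyte-like and 2.31-fold higher (1.62 to 3.36) in macrophage-like nuclei, the latter 2.40-fold higher (1.89 to 3.08) in macrophage-like nuclei (0.67 on the log2 scale at 5% mitochondrial UMIs), also led an unnamed low-depth cluster that held 537 nuclei of the sedentary and 757 of the running library. The cardiomyocyte-like share ratio was 0.731 (0.663 to 0.806), the fibroblast-like 0.939 (0.883 to 0.999), or 1.08 in female-weighted nuclei, and the vascular endothelial-like 0.999 (0.919 to 1.09), or 2.23 at 5% mitochondrial UMIs. The macrophage-like ratio was 1.16 (0.960 to 1.40), or 0.404 in female-weighted nuclei, few in the running library.

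Heat shock medians were -0.76, -1.01, -1.52 and -0.89 in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei. The medians in Y-positive and Y-negative nuclei were -1.23 and -0.11 for the first, -1.46 and -0.34 for the second and -2.08 and -0.87 for the third. Hsph1 was 3.83-fold lower (3.07 to 4.81) in cardiomyocyte-like nuclei, but its log2 ratio was -3.44 in Y-positive and 0.19 in Y-negative nuclei, and in vascular endothelial-like nuclei Hspa1b was 13.4-fold lower (7.77 to 25.1). Clock medians were 0.34, 0.29, 0.52 and 0.22 in the same order, the last inside the range of random lists. The clock output gene Dbp was 2.70-fold higher (2.20 to 3.32) in cardiomyocyte-like and 3.11-fold higher (2.23 to 4.41) in vascular endothelial-like nuclei, and Arntl was 6.29-fold lower (4.04 to 10.2) in the latter. In Y-positive nuclei the log2 ratio of Arntl was -2.35 in cardiomyocyte-like and -3.42 in vascular endothelial-like nuclei. Of the 30 values of genes taken by size or fixed beforehand, 12 moved by over 1.5-fold in Y-positive and 13 in Y-negative nuclei. The running library had the highest mitochondrial percentage and the sedentary library high heat shock RNA, so differences between these 2 libraries carry both.

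The comparison of the running infarct with the sedentary infarct library asks how infarcted hearts differed after prior running. In cardiomyocyte-like nuclei Nppa was 1.22-fold lower (1.10 to 1.37), Nppb 1.2-fold higher (1.07 to 1.35) and Ankrd1 1.13-fold lower (1.09 to 1.18), and in fibroblast-like nuclei Postn was 1.29-fold lower (1.24 to 1.35) and Col1a1 1.16-fold higher (1.07 to 1.25). The matrix genes Eln, 1.98-fold higher (1.88 to 2.08), Fbn1, 1.65-fold higher (1.57 to 1.72), and Col3a1, 1.59-fold higher (1.53 to 1.65), were higher in the latter. Macrophage-like nuclei made up 13.9% (12.9 to 14.9) against 8.39% (7.44 to 9.41) of nuclei, and fibroblast-like nuclei 16.2% (15.2 to 17.3) against 29.0% (27.4 to 30.7). Clock genes differed in every main class, with Dbp 2.56-fold lower (1.96 to 3.39) in cardiomyocyte-like nuclei.

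In cardiomyocyte-like nuclei the stress and fetal list had 2 of 12 genes at least 1.5-fold higher (median 0.26, percentile 99.97) and a median of -0.01 with doublets kept. Nppb turned to -0.12 under that setting, and Ankrd1 to 0.19 in Y-positive nuclei. Nuclear-encoded oxidative phosphorylation had a median of 0.19, percentile 99.99, with the ATP synthase gene Atp5b 1.37-fold higher (1.24 to 1.51), but a median of -0.09 without the low-depth clusters. Fatty acid oxidation (-0.09, percentile 14.3), glycolysis (-0.06, percentile 41.1), calcium handling (0.08, percentile 91.4, or -0.20 with doublets kept) and sarcomere genes (-0.02, percentile 35.1) had smaller medians. The growth factor homologue gene Fgf12 was 24.3-fold higher (14.9 to 42.4) and the transporter gene Slc16a12 6.17-fold higher (4.06 to 9.65). In the running infarct library 10 of 390 nuclei held 95.1% of Fgf12 and 91.6% of Slc16a12 UMIs, and with doublets kept the log2 ratios were 2.02 and 0.78 in place of 4.60 and 2.63. Smooth muscle actin, Acta2, was 3.24-fold higher (2.27 to 4.68), or 0.82 on the log2 scale with doublets kept, the carboxylesterase gene Ces1d 2.15-fold lower (1.90 to 2.44) and the clock repressor Ciart 3.05-fold lower (2.03 to 4.76).

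In fibroblast-like nuclei collagen and extracellular matrix genes had a median of 0.19, above all 10000 matched random lists (3 of 25 measured genes at least 1.5-fold higher and 0 lower), 0.21 in Y-positive and 0.07 in Y-negative nuclei, myofibroblast activation genes 0.08, percentile 96.5 and TGF-beta signalling genes 0.03, percentile 78.0. Homeostatic genes had 4 of 16 lower (median -0.29, below all 10000 matched random lists), with Inmt 2.38-fold lower (1.79 to 3.2) and the actin-severing gene Gsn 1.62-fold lower (1.54 to 1.70). Interferon response genes had a median of 0.41, above all 10000 matched random lists, with the ubiquitin ligase gene Rnf213 1.38-fold higher (1.25 to 1.53). The actin regulator Kank4 was 4.07-fold higher (2.91 to 5.78), the potassium channel subunit gene Kcnip1 2.78-fold lower (2.35 to 3.30), the matricellular gene Sparcl1 2.87-fold lower (2.27 to 3.65) and Stac 4.36-fold higher (2.69 to 7.34), the last with 68.8% of its UMIs in 10 nuclei. The smooth muscle myosin gene Myh11 was 3.81-fold lower (2.41 to 6.27), with 92.4% of its UMIs in the sedentary infarct library in 10 nuclei. Neither Myh11 here nor Acta2 in cardiomyocyte-like nuclei was checked for background against smooth muscle-like nuclei. The Postn-led cluster supplied 30.1% of the class in the sedentary infarct and 43.1% in the running infarct library.

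In vascular endothelial-like nuclei arterial genes had 4 of 10 lower (median -0.54, below all 10000 matched random lists), flow response genes 2 of 9 (median -0.33, percentile 0.1) and venous genes 2 of 4 (median -0.56, percentile 0.02), with the clotting factor gene Vwf 1.58-fold lower (1.35 to 1.84). The angiogenesis median was 0.04, percentile 76.6, with Col4a1 1.33-fold higher (1.22 to 1.45). The glypican gene Gpc4 was 2.51-fold higher (1.70 to 3.81), or a log2 ratio of 0.72 without the low-depth cluster, the scaffold gene Dlg2 1.89-fold higher (1.65 to 2.18) and the glucocorticoid-induced factor Zbtb16 2.06-fold lower (1.78 to 2.39). In macrophage-like nuclei the resident list had 2 of 10 lower (median -0.34, percentile 0.1), the monocyte-derived list a median of -0.04, percentile 30.5, or 0.39 over genes with at least 500 UMIs, and the lipid-associated list 0.04, percentile 56.3, or -0.28 with at least 800 genes. The transcription factor gene Prdm1 was 2.60-fold higher (1.65 to 4.26), Rap1gap2 2.05-fold higher (1.62 to 2.60), Dcakd 2.14-fold higher (1.61 to 2.89), the glucocorticoid-induced factor Klf9 2.88-fold lower (2.13 to 3.94) and the growth factor receptor gene Fgfr1 2.55-fold lower (2.11 to 3.09). With at least 800 genes per nucleus, the log2 ratios were 0.61 for Prdm1, -0.76 for Fgfr1 and 0.01 for Adamts10, a metalloprotease gene at -1.15 over all nuclei.

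The share ratio was 1.66 (1.44 to 1.90) for macrophage-like, 1.76 (1.31 to 2.37) for T cell-like, 1.46 (1.31 to 1.63) for vascular endothelial-like, 0.714 (0.624 to 0.818) for cardiomyocyte-like (0.472 male-weighted), 0.559 (0.513 to 0.608) for fibroblast-like and 0.535 (0.389 to 0.736) for pericyte-like nuclei. Outside its low-depth cluster the vascular endothelial-like share was not higher in the running infarct library. An unnamed low-depth cluster led by matrix and globin genes held 2.98% of the sedentary infarct and 6.62% of the running infarct library. Clock medians were -0.57, -0.64, -0.71 and -0.84 in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei. Arntl was 2.98-fold higher (2.51 to 3.54), Npas2 3.15-fold higher (2.58 to 3.86) and Nr1d1 2.47-fold lower (2.08 to 2.95) in fibroblast-like nuclei, each in the other direction than in the running over sedentary comparison. In vascular endothelial-like nuclei Arntl was 2.39-fold higher (1.57 to 3.76), or 3.38 on the log2 scale in Y-positive nuclei, Nr1d1 2.75-fold lower (1.88 to 4.05) and Dbp 2.65-fold lower (1.88 to 3.75). Nuclei of the running infarct library were shallower, and 16 of the 30 values of genes taken by size or fixed beforehand moved by over 1.5-fold in Y-positive nuclei against 1 in Y-negative nuclei.

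**Figure D3:**
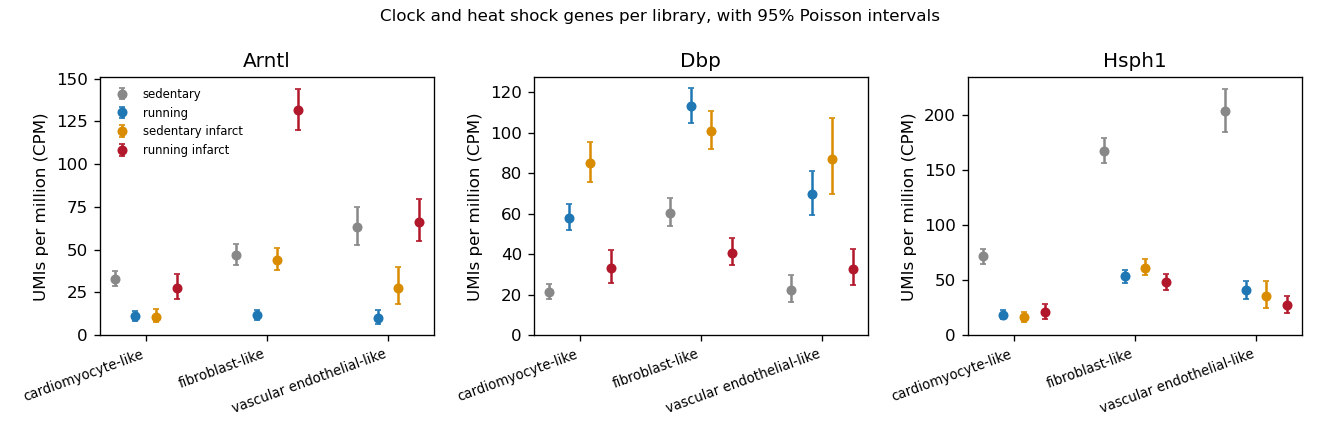
CPM of the clock genes Arntl and Dbp and the chaperone gene Hsph1 in 3 classes of the 4 libraries, with exact 95% Poisson intervals as bars. Arntl in fibroblast-like nuclei stood at 47.1, 11.8, 44.2 and 132 CPM, and Hsph1 was highest in the sedentary library in each class shown.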

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

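Every test of an explanation in this part was chosen after the result had been seen. Some results went in opposite directions in runners and sedentary mice or in Y-positive and Y-negative nuclei, and none of these differences was tested, since each group has 1 library. The infarct ratio of the vascular endothelial-like share was 1.11 in runners and 0.759 in sedentary mice, a ratio of 1.46. The runners' ratio fell below 1 in some settings, to 0.984 with at least 800 genes, 0.857 in male-weighted nuclei and 0.525 at 5% mitochondrial UMIs, where the sedentary one was 1.00. The infarct response of the clock list was -0.53 in runners and 0.34 in sedentary mice in cardiomyocyte-like nuclei, a difference of -0.87, and -0.77 and 0.32 in vascular endothelial-like nuclei, a difference of -1.09. In cardiomyocyte-like nuclei of the running over the sedentary library, the Y-positive and Y-negative medians were -0.31 and 0.37 for stress and fetal cardiac genes, a difference of -0.68. They were 0.37 and -0.45 for fatty acid oxidation, a difference of 0.82, and -0.58 and 0.27 for the hypoxia response, a difference of -0.85. In sedentary infarct over sedentary, the hypoxia medians were -0.77 and 0.42, a difference of -1.19.

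Heat shock genes stood lower in the running than in the sedentary library in every main class. They were also lower in the sedentary infarct library, which had not run. The state or handling of 1 heart of the sedentary pool is a candidate explanation: within the sedentary library the list was higher in Y-positive than in Y-negative nuclei, by 1.07, 0.84 and 0.62 on the log2 scale in cardiomyocyte-, fibroblast- and vascular endothelial-like nuclei, a median of 0.835, against -0.07, -0.45 and -0.43 in the running library. Sex and heart are confounded in that split, so a difference between sexes stays open. Free RNA stays open as well: the sedentary library added 488, 488, 996 and 404 CPM in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei, highest over lowest 2.47, between the 1.5 that free RNA would allow and the 4 set to exclude it. Running itself cannot be told apart from these, since the list's median over classes was -0.338 in Y-negative nuclei, of the same sign but part male.

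Clock genes differed between the libraries with and without running, although without infarct the macrophage-like list median of 0.22 lay inside the range of random lists. RNA quality or depth is argued against: members on the Arntl side and on the Nr1d1 side had the same sign in 0 of 8 pairs of class and comparison. The difference between the sides was -0.98, -1.82, -2.07 and -0.75 for running over sedentary and 0.92, 2.31, 2.01 and 1.03 for running infarct over sedentary infarct, in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei. These signs are opposite in 4 of 4 classes, an observation rather than a separate test, and running acting alike with and without infarct would not give them by itself. Hearts taken at different phases of the clock may be the source, since the sides had opposite signs in 8 of 8 pairs. Without infarct the list median was 0.43 and 0.01 in Y-positive and Y-negative cardiomyocyte-like and 0.56 and 0.04 in such fibroblast-like nuclei. Arntl was lower in Y-negative nuclei too, at log2 ratios of -0.25 and -1.14, yet a difference between sexes or single hearts stays open. The time of day at harvest is not in the labels, and a shift of phase by running that depends on infarct was not tested.

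The running infarct library held a higher macrophage-like and a lower fibroblast-like share than the sedentary infarct library. Shallower nuclei in the running infarct library are argued against for the macrophage-like share, as its ratio was 1.94 with at least 800 genes. The fibroblast-like ratio was 0.673 under that filter, closer to 1, so depth stays open as a part of it. The sex mix of the pools is argued against as the whole source, since the lower of the female- and male-weighted ratios was 1.39. Fibroblast nuclei left in the unnamed low-depth cluster led by matrix genes are argued against as the whole source of the lower fibroblast-like share, whose ratio of 0.559 became 0.714 with that cluster counted in, so they may be a part of it. Infarct size, the region sampled, differences between single hearts and prior running itself may each matter and were not tested.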

How the results depend on the processing

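The settings chosen after seeing the data are listed with the processing and include at most 5% mitochondrial UMIs, first planned as the main limit. No paired analysis was possible because each group has 1 library. The stricter filter, at least 800 genes and at most 1% mitochondrial UMIs, left 6, 0, 137 and 91 nuclei and gave no value. Against counting error, 136 of 188 share ratios stayed within their interval, 47 left it and 5 changed side. For list medians the numbers were 2038, 279 and 24 of 2341, and for log2 ratios of single genes 2852, 619 and 36 of 3507. A change of side was counted only for values that lay off no difference to begin with, and some values close to it also changed sign. Of the 6 genes taken by size per comparison and class, between 2 and 6 were also taken at a background limit of 2. The values that moved among the main results, and all that changed side, follow by setting, and the cause was not tested.

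At 5% mitochondrial UMIs, the share ratios were 0.661 (cardiomyocyte-like), 0.708 (fibroblast-like) and 2.23 (vascular endothelial-like) for running over sedentary, and 0.428 (cardiomyocyte-like) and 1.00 (vascular endothelial-like) for sedentary infarct over sedentary. Others were 0.531 (cardiomyocyte-like), 0.791 (fibroblast-like) and 0.525 (vascular endothelial-like) for running infarct over running, and 0.820 (cardiomyocyte-like), 1.16 (vascular endothelial-like) and 1.95 (macrophage-like) for running infarct over sedentary infarct. At Leiden resolution 0.5, the share ratios were 0.945 (cardiomyocyte-like) for running over sedentary, and 4.33 (macrophage-like) for running infarct over running. Another was 0.980 (cardiomyocyte-like) for running infarct over sedentary infarct. In male-weighted nuclei, the share ratios were 0.839 (cardiomyocyte-like) for running over sedentary, and 0.867 (cardiomyocyte-like) and 0.523 (vascular endothelial-like) for sedentary infarct over sedentary. Others were 0.487 (cardiomyocyte-like), 0.857 (vascular endothelial-like) and 2.53 (macrophage-like) for running infarct over running, and 0.472 (cardiomyocyte-like) and 1.39 (macrophage-like) for running infarct over sedentary infarct. In female-weighted nuclei, the share ratios were 1.08 (fibroblast-like), 1.09 (vascular endothelial-like) and 0.404 (macrophage-like, few nuclei) for running over sedentary, and 0.503 (cardiomyocyte-like), 0.906 (fibroblast-like) and 0.851 (vascular endothelial-like) for sedentary infarct over sedentary. Others were 0.475 (fibroblast-like), 1.22 (vascular endothelial-like) and 12.3 (macrophage-like, few nuclei) for running infarct over running, and 0.958 (cardiomyocyte-like) and 1.92 (macrophage-like) for running infarct over sedentary infarct. With each library clustered alone, the share ratios were 1.17 (vascular endothelial-like) and 0.874 (macrophage-like) for running over sedentary, and 0.637 (vascular endothelial-like) and 1.40 (macrophage-like) for sedentary infarct over sedentary. Others were 2.05 (vascular endothelial-like) and 1.90 (macrophage-like) for running infarct over sedentary infarct. With doublets kept, the share ratios were 1.15 (fibroblast-like) for sedentary infarct over sedentary, and 0.833 (fibroblast-like) and 4.26 (macrophage-like) for running infarct over running. Another was 0.682 (fibroblast-like) for running infarct over sedentary infarct. With at least 800 genes, the share ratios were 0.550 (cardiomyocyte-like), 0.735 (fibroblast-like) and 0.984 (vascular endothelial-like) for running infarct over running, and 0.586 (cardiomyocyte-like), 0.673 (fibroblast-like) and 1.94 (macrophage-like) for running infarct over sedentary infarct. Over all deposited barcodes, the share ratios were 0.562 (fibroblast-like) and 4.30 (macrophage-like) for running infarct over running. At a doublet-score limit of 0.09, the share ratio was 4.27 (macrophage-like) for running infarct over running.

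Over genes with at least 20 UMIs, the list medians were 0.027 (lipid-associated) for running over sedentary, and 1.72 (stress and fetal) and 1.16 (monocyte-derived) for sedentary infarct over sedentary. Others were 0.71 (angiogenesis) and 0.67 (monocyte-derived) for running infarct over running. Over genes with at least 500 UMIs, the list medians were -0.090 (stress and fetal) and -0.21 (angiogenesis) for running over sedentary, and 0.85 (stress and fetal) for sedentary infarct over sedentary. Others were -0.017 (glycolysis) and 0.24 (angiogenesis) for running infarct over running, and 0.29 (angiogenesis) and 0.39 (monocyte-derived) for running infarct over sedentary infarct. With every nucleus weighed the same, the list median was -0.0096 (calcium handling) for running infarct over running. In Y-negative nuclei, the list medians were 0.37 (stress and fetal), 0.27 (cardiomyocyte hypoxia) and 0.022 (collagen and matrix) for running over sedentary, and 1.10 (stress and fetal) and 0.88 (collagen and matrix) for sedentary infarct over sedentary. Others were 1.53 (stress and fetal), 0.98 (collagen and matrix) and 0.23 (angiogenesis) for running infarct over running, and 0.069 (collagen and matrix) for running infarct over sedentary infarct. In Y-positive nuclei, the list medians were -0.31 (stress and fetal), -0.17 (glycolysis), -0.33 (collagen and matrix), -0.15 (homeostatic) and -0.29 (angiogenesis) for running over sedentary, and 0.68 (stress and fetal) for sedentary infarct over sedentary. Others were -0.057 (cardiomyocyte hypoxia) for running infarct over running, and -0.11 (oxidative phosphorylation) for running infarct over sedentary infarct. At a doublet-score limit of 0.09, the list medians were -0.063 (lipid-associated) for sedentary infarct over sedentary, and -0.10 (monocyte-derived) for running infarct over running. Another was -0.31 (monocyte-derived) for running infarct over sedentary infarct. With doublets kept, the list medians were 0.82 (stress and fetal) and -0.041 (lipid-associated) for sedentary infarct over sedentary, and 0.96 (stress and fetal) and -0.34 (calcium handling) for running infarct over running. Others were -0.0086 (stress and fetal), -0.15 (oxidative phosphorylation) and -0.19 (cardiomyocyte heat shock) for running infarct over sedentary infarct. At 5% mitochondrial UMIs, the list medians were -0.12 (glycolysis), -0.068 (collagen and matrix), -0.057 (homeostatic), -0.32 (angiogenesis), 0.095 (flow response) and 0.18 (arterial) for running over sedentary, and 0.61 (angiogenesis) for sedentary infarct over sedentary. Others were 0.96 (collagen and matrix), 0.13 (venous) and -0.52 (monocyte-derived) for running infarct over running, and 0.098 (stress and fetal) and 0.053 (collagen and matrix) for running infarct over sedentary infarct. With at least 800 genes, the list medians were 0.042 (monocyte-derived) for running over sedentary, and -0.030 (monocyte-derived) for sedentary infarct over sedentary. Without nuclei over 20000 UMIs, the list median was -0.014 (oxidative phosphorylation) for running infarct over sedentary infarct. Without the low-depth clusters, the list medians were 0.14 (angiogenesis) for running infarct over running, and -0.094 (oxidative phosphorylation) and -0.035 (cardiomyocyte heat shock) for running infarct over sedentary infarct.

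With every nucleus weighed the same, the log2 ratios were -1.99 (Nppa) and -0.033 (Vegfc) for running over sedentary, and -0.026 (Myh7) for running infarct over sedentary infarct. In Y-negative nuclei, the log2 ratios were -0.59 (Nppa), 1.00 (Egln3), 0.32 (P4ha1), 0.19 (cardiomyocyte-like Hsph1), 0.082 (Bag3), -0.074 (Vegfc) and 0.10 (macrophage-like Hsph1) for running over sedentary, and 0.10 (vascular endothelial-like Arntl) for sedentary infarct over sedentary. In Y-positive nuclei, the log2 ratios were -0.085 (Nrp1) for running over sedentary, and 0.19 (Ankrd1), -0.19 (Atp5a1), -0.11 (Atp5b) and 0.20 (Ephb4) for running infarct over sedentary infarct. With doublets kept, the log2 ratios were -0.26 (Myh7) for sedentary infarct over sedentary, and -0.44 (Myh7) for running infarct over running. Others were -0.12 (Nppb), -0.062 (Myh7), -0.17 (Atp5a1), -0.0053 (Atp5b) and -0.021 (cardiomyocyte-like Hspa8) for running infarct over sedentary infarct. At 5% mitochondrial UMIs, the log2 ratios were 0.38 (Edn1), -0.14 (Nrp1), -0.10 (Rnf213) and 0.045 (Cd44) for running over sedentary, and -0.16 (Dkk3) and 0.22 (vascular endothelial-like Hspa8) for running infarct over running. Another was -0.028 (Nppb) for running infarct over sedentary infarct. With at least 800 genes, the log2 ratios were 0.23 (Gsta3) for sedentary infarct over sedentary, and 0.0082 (Adamts10) and -0.0007 (Mrc1) for running infarct over sedentary infarct. Without the low-depth clusters, the log2 ratios were -0.0061 (Atp5a1), -0.026 (Atp5b) and 0.030 (Vegfc) for running infarct over sedentary infarct.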

Other observations

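Endothelium outside the blood capillaries and arteries, mural cells and the interferon programme were followed as well. Lymphatic endothelial-like nuclei made up 3.48, 4.15, 2.27 and 2.46% of nuclei in the sedentary, running, sedentary infarct and running infarct libraries. Their share was lower after infarction, with ratios of 0.653 (0.498 to 0.857) in sedentary mice and 0.593 (0.477 to 0.738) in runners. Endocardial-like nuclei made up 7.96, 8.73, 7.01 and 8.87%, pericyte-like nuclei 1.94, 1.68, 2.66 and 1.42%, smooth muscle-like nuclei 0.763, 0.789, 0.8 and 1.04% and Schwann cell-like nuclei 0.0782, 0.377, 0.0320 and 0.127%. The pericyte-like ratio of infarct over no infarct was 1.37 (1.03 to 1.83) in sedentary mice and 0.846 (0.622 to 1.15) in runners.

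Interferon response genes in the running over the sedentary library had medians of 0.59, 0.22, 0.30 and 0.29 in cardiomyocyte-, fibroblast-, vascular endothelial- and macrophage-like nuclei, although the first holds mostly RNA that stands higher in other classes. In the same order 3 of 6, 0 of 14, 4 of 14 and 2 of 6 members were at least 1.5-fold higher. The medians in Y-positive and Y-negative nuclei were 0.74 and 0.09 for the first class, 0.36 and 0.07 for the second and 0.57 and 0.09 for the third. There Rnf213 turned from 0.19 to -0.10 at 5% mitochondrial UMIs, a setting chosen after seeing the data. The running infarct library had a median of -0.29 over the running library in that class and 0.33 over the sedentary infarct library in macrophage-like nuclei. Endothelial-to-mesenchymal genes had medians of 0.17, 0.33, 0.07 and 0.23 for sedentary infarct over sedentary, running infarct over running, running over sedentary and running infarct over sedentary infarct. Venous genes had 0.09, -0.49, 0.07 and -0.56 in the same order, but at 5% mitochondrial UMIs the second was 0.13 and the third -0.28, and the first was -0.32 in Y-positive nuclei. Without background members the second was -0.16. Ion channels and gap junctions in cardiomyocyte-like nuclei had -0.12, -0.03, 0.01 and 0.00, and exercise-linked growth signalling -0.18, -0.14, -0.09 and 0.00. Hypoxia response medians in fibroblast-like nuclei were -0.12, 0.06, -0.14 and 0.00.

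Cell cycle genes were sparse, with 2 to 4 of the list measured, and medians in fibroblast-like nuclei of 0.10, 0.46, -0.13 and 0.16. After thinning, any of them had a UMI in 12.6, 16.2, 13.6 and 14.8% of cardiomyocyte-like, 20.3, 20.9, 23.4 and 22.2% of fibroblast-like, 15.2, 16.9, 18.1 and 17.6% of vascular endothelial-like and 21.8, 30.0, 28.9 and 26.5% of macrophage-like nuclei of the 4 libraries, from which no cycling is read. Fgf12 stood at 1.55, 57.8, 5.04 and 123 CPM in cardiomyocyte-like nuclei of the 4 libraries, a gene looked at across libraries after its values were seen. Globin RNA summed to 235, 1144, 410.0 and 365 CPM in vascular endothelial-like nuclei.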
